A study of Homo sapiens with 4 samples.

How the data were processed

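Poly(A) RNA from Panc1 cells was sequenced in 4 libraries, 2 labelled HMGB2 siRNA and 2 labelled scramble siRNA. RNA was isolated with TRIzol and a column kit and libraries were built by a sequencing company, per the labels' protocols. Reads were aligned with STAR and handled with SAMtools 1.9, and featureCounts of Subread 1.6.3 and DESeq2 are also named, with the human build hg38 (GRCh38), per the submitters' processing notes. The deposited values are unnormalized whole-number read counts per gene summed over the exons listed in the file, 1 table per library, per the file headers. Strand setting, treatment of multimapping reads and treatment of overlapping genes were not given in the sources used here. Each table held 54628 genes named by symbol, with the exon coordinates used below. Of these gene names 3951 also had exons on alternative sequences of the assembly, where reads that map equally well to both copies could be left uncounted or counted again. No rows without a gene name were found (0 in each table).

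Each table was assigned to its sample as recorded in the deposit, and each sample to its group by its treatment label. The file names and the headers of the count columns name the opposite treatment in all 4 tables, and this contradiction was left as it stands. Nothing was regrouped after the values were seen. Direction was coded as labelled HMGB2 siRNA minus labelled scramble, and HMGB2 was examined before other genes because it checks the labels.

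The counts were tested with the quasi-likelihood test of edgeR 4.0.16 (glmQLFit and glmQLFTest) in R 4.3.3, with the group as the only term, TMM scaling and the default filterByExpr filter (smallest count 10, smallest total 15). This left 15161 genes. The p-values were adjusted by the Benjamini-Hochberg method and genes with an adjusted p under 0.05 were called. CPM values used TMM-scaled library sizes. The common biological coefficient of variation was 0.0507. A single value compared over 2 against 2 libraries cannot give a two-sided exact permutation p below 0.333, so all tests rest on the spread shared between genes.

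Before the data were examined, 31 gene lists, the rule for named genes, the main tests and most alternatives were fixed. Named genes were HMGB2, HMGB1 and HMGB3, the 12 genes with the largest change in each direction among genes with a symbol, an adjusted p under 0.05, a mean of at least 5 CPM and non-overlapping groups, and up to 4 members of each list with the smallest p. Where no member of a list passed, the 2 with the highest mean CPM were given as values, as were genes for a check of cell identity, among them CDKN2A and SMAD4. Some genes and 2 lists given by these rules are not reported here, and none was added. Lists with at least 5 tested members (29) were tested with camera of limma 3.58.1 on voom values with a preset correlation of 0.01, without HMGB2. Camera with an estimated correlation and fry, which tests whether the genes of a list move on balance in the same direction, were run beside it. The lists share 33 genes that stand in more than 1 list.

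The alternatives were RLE, upper-quartile and total-count scaling, no low-count filter, a minimum mean of 1 CPM, DESeq2 1.42.0, limma-voom, a replicate block, a test against a 1.5-fold change (glmTreat) and leaving out each library in turn. Libraries thinned to the smallest total, and lists without genes that carry the associated 3′UTR words, were added after seeing the data. The edgeR procedure was tested on simulated counts of 14923 genes with the means and library sizes of this comparison of labelled groups, with 50 genes changed at each fold. It recovered 32.0% of genes changed 1.25-fold, 67.3% of those changed 1.5-fold, 81.6% of those changed 2-fold and 98.0% of those changed 4-fold, with 2 false calls.

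To look for traces of siRNA seeds, 3′UTR sequences were taken from the GENCODE annotation of GRCh38 for 12091 tested genes. Sequences were matched by gene symbol and short ones were left out. The other 3069 tested genes had no matched 3′UTR, among them H2AC6, H2BC5, H1-2 and CCN2. For each of 16383 heptamers present in at least 20 genes, the log2 fold change was regressed on presence of the heptamer with 3′UTR length and GC content as covariates, and p-values were Bonferroni-adjusted. The associated words named in the text as left out are the 9 with higher values and an adjusted p under 0.001. They were chosen on these same fold changes, so leaving out genes that carry them favours lower list values. Genes without a matched 3′UTR were left out with them, so the histone and mitochondrial lists were not tested in that alternative. A planted heptamer with an effect of 0.15 was estimated at 0.162 in simulated data. Intervals of medians are 95% bootstrap intervals that resample genes as if independent, so they do not measure the spread between libraries. Scripts used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.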

Results

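Gene expression was measured by sequencing of poly(A) RNA from Panc1, an established human cell line from a pancreatic ductal carcinoma. The labels put 2 libraries in a group treated with small interfering RNA (siRNA) against HMGB2, a chromatin protein of the high mobility group box family, and 2 libraries in a control group treated with scramble siRNA. The question posed by this design was which transcripts depend on HMGB2. The total gene counts of the libraries labelled HMGB2 siRNA were 31852391 and 20976561, and those of the libraries labelled scramble were 21874647 and 20340695. A gene without reads in a library could still have had up to 3 counts of that total, which is 0.0954 to 0.146 CPM (counts scaled to a common library total), a limit that covers counting error only. The labels number the libraries within each group but do not say that they came from separate cultures, so the p-values below measure the spread between these libraries, which may be technical. The 2 libraries of each group differed by more than sampling noise, with chi-square values per degree of freedom of 3.13 and 5.65.

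HMGB2 (GRCh38 chromosome 4, 173331376 to 173334358, minus strand) went against the labels. Its exons had 4021 and 2746 counts in the libraries labelled HMGB2 siRNA and 346 and 319 counts in the libraries labelled scramble. These counts corresponded to 131 ± 4.2 CPM (SD, n = 2) and 15.5 ± 0.29 CPM (SD, n = 2). HMGB2 was therefore 8.43-fold higher in the libraries labelled HMGB2 siRNA, a log2 fold change of 3.07 ± 0.08 (SE; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 1.54e-33). In all 4 deposited tables the column of counts was also headed with the other treatment than the label of its sample. Groups are named below as the labels name them, and every direction is that of the libraries labelled HMGB2 siRNA, which had the higher HMGB2, against the libraries labelled scramble, which had the lower HMGB2. The paralogs moved little. HMGB1 (chromosome 13, 30456704 to 30617597) had 593 ± 13 against 527 ± 22 CPM (SD, n = 2 each), a log2 fold change of 0.17 ± 0.06 (SE) with an adjusted p of 0.0371, and this call was lost with upper-quartile or total-count scaling, with the replicate block, in thinned libraries and without any library but scramble replicate 1. HMGB3 (chromosome X, 150980507 to 150990773) had 376 ± 17 against 348 ± 15 CPM (SD, n = 2 each) and did not pass the test (adjusted p = 0.21), although it did without scramble replicate 1 (adjusted p = 0.0244).

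**Figure D1:**
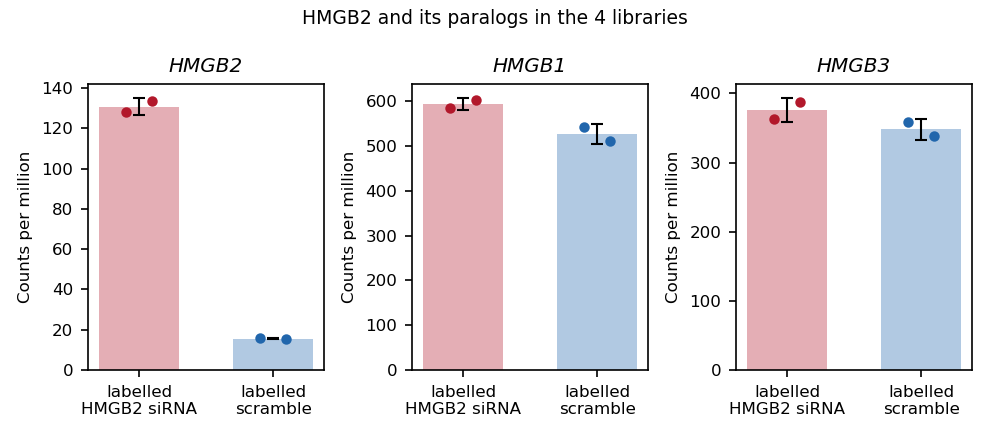
CPM (vertical axes, from 0) of HMGB2, HMGB1 and HMGB3 in the libraries labelled HMGB2 siRNA (red) and labelled scramble siRNA (blue); points are libraries, bars the means and error bars the SD of 2 libraries. HMGB2 was 131 CPM in the libraries labelled HMGB2 siRNA and 15.5 CPM in those labelled scramble, while HMGB1 and HMGB3 differed by 1.13-fold and 1.08-fold.

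After HMGB2, the genes reported here with the largest higher values in the libraries labelled HMGB2 siRNA (the HMGB2-high libraries) were SLC9A2, a sodium-proton exchanger, CRMA, and MAT2B, the regulatory subunit of methionine adenosyltransferase. SLC9A2 (chromosome 2, 102619553 to 102711355) had 8.58 ± 1.2 against 1.63 ± 0.064 CPM (SD, n = 2 each) and was 5.28-fold higher. CRMA was 4.26-fold higher, and MAT2B had 81.1 ± 0.22 against 19.7 ± 2.8 CPM (SD, n = 2 each) and was 4.12-fold higher. PMP22, SRGN, SEC23A, which encodes a component of the COPII vesicle coat, MYPOP, LIN28B, an inhibitor of let-7 microRNA maturation, CEP97 and TWSG1 rose by 3.07-fold to 3.95-fold. In the other direction, HAS3, a hyaluronan synthase (chromosome 16, 69105653 to 69118719), had 9.66 ± 1.9 against 34.1 ± 3.8 CPM (SD, n = 2 each), a log2 fold change of -1.84 ± 0.11 (SE). BATF3, a transcription factor, followed at -1.61 ± 0.20, the histone gene H2AC6 at -1.43 ± 0.10, the chemokine gene CXCL1 at -1.38 ± 0.19 and FILIP1L at -1.36 ± 0.15 (log2 fold change ± SE). WDFY1, the most abundant of these, had 45.2 ± 1.6 against 105 ± 8.2 CPM (SD, n = 2 each), and H2BC21, DOK4, KLHL8, PARD6G and H2BC5 had log2 fold changes from -1.15 to -1.07. C2orf72 had 3.45 ± 0.74 against 7.06 ± 0.41 CPM (SD, n = 2 each). All 24 genes with the largest changes, 1 of them not reported here by name, passed the edgeR test, with adjusted p from 1.54e-33 to 3.25e-05. At least 1 of the heptamers GACAAAG, ATAGTAA and AATAGTA was present in the 3′ untranslated region (3′UTR) of all 10 of the genes with the largest higher values, other than HMGB2, that had a matched 3′UTR, and in 0 of 9 such genes in the other direction. These heptamers were chosen for their association with the fold changes of the same genes, so the contrast is no independent test. HAS3 shares exonic sequence with CHTF8 and DERPC, SEC23A with SEC23A-AS1, DOK4 with POLR2C and C2orf72 with an uncharacterised gene, each on the opposite strand, and their reads cannot be separated without knowing whether strand was used in counting.

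**Figure D2:**
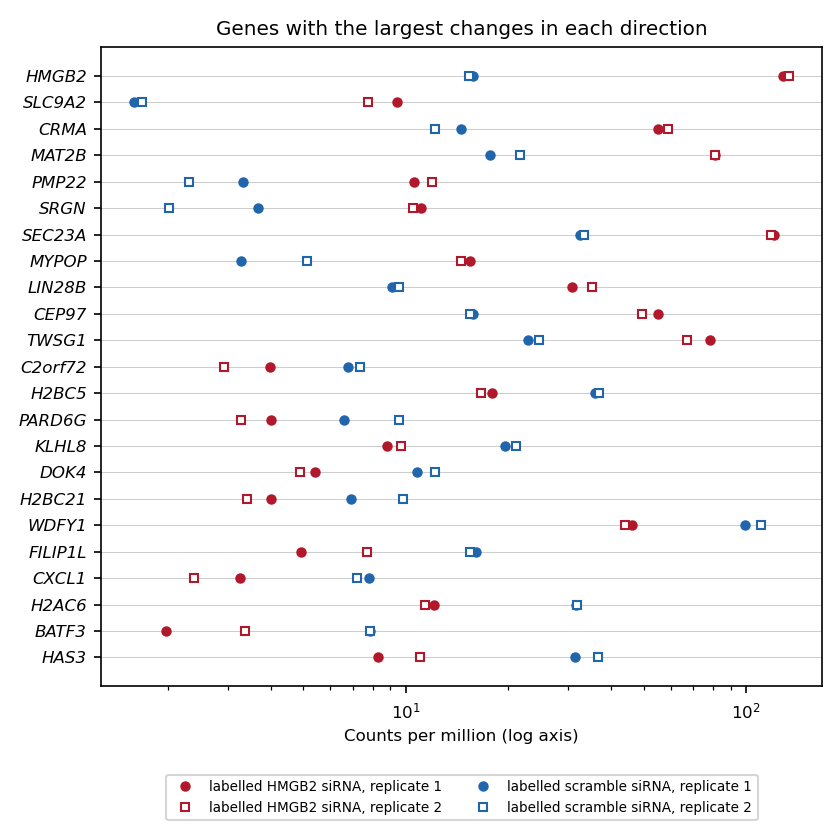
CPM (horizontal log axis) of the genes with the largest change in each direction that are reported here, in each library labelled HMGB2 siRNA (red) and labelled scramble siRNA (blue); circles are replicate 1 and squares replicate 2. The groups do not overlap for any of these genes, and the points of HMGB2, at the top, lie farthest apart.

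Of 15161 genes tested, 2536 were higher and 2135 were lower in the libraries labelled HMGB2 siRNA (the HMGB2-high libraries), and 10490 did not pass. The median log2 fold change was 0.40 over the genes called higher and -0.40 over those called lower. More than 2-fold changes were found for 233 genes called higher and 208 called lower. For 63.7% of the tested genes both libraries of 1 group lay above both of the other, where chance gives 33.3%. With TMM scaling 54.3% of the called genes were higher, but this share was 42.0% with upper-quartile factors and 43.3% with total counts, so the balance of directions depended on the scaling. DESeq2 called 1922 genes higher and 1286 lower, so that 59.9% of its calls were higher, and gave no adjusted p for 2352 genes. A test against a 1.5-fold change called 213 higher and 45 lower. Without replicate 1 labelled HMGB2 siRNA 1481 genes were higher and 903 lower, and without replicate 2 of that label 1603 were higher and 1024 lower.

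Mitotic genes had the largest share of called members among the 29 lists tested. Of 46 G2/M and mitosis genes, 44 rose in the libraries labelled HMGB2 siRNA (the HMGB2-high libraries), 0 fell, and 46 passed when adjusted over the list alone, with a median log2 fold change of 0.58. PLK1, a mitotic kinase, had 164 ± 0.40 against 89.6 ± 12 CPM (SD, n = 2 each) and was 1.83-fold higher. The kinases AURKA and TTK were 1.65-fold and 1.69-fold higher and the spindle motor KIF11 1.65-fold higher. The list stood apart from other genes by camera with its preset correlation of 0.01 (adjusted p = 2.7e-35), but not when the correlation was estimated from the 2 residual degrees of freedom (adjusted p = 0.417 with an estimated correlation). Among 44 G1/S and DNA replication genes, 30 rose, 2 fell and 12 did not pass, and 32 and 2 passed when adjusted over the list alone. The ribonucleotide reductase subunit RRM2 had 401 ± 7.3 against 252 ± 30 CPM (SD, n = 2 each), and GINS1 and MCM7, parts of the replicative helicase, were 1.63-fold and 1.44-fold higher. The median of this list was 0.30 on the log2 scale (camera adjusted p = 2.26e-09; adjusted p = 0.579 with an estimated correlation). PLK1 shares exonic sequence with ERN2 and RRM2 with an uncharacterised gene, both on the opposite strand.

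In the list named for cohesin, condensin and CTCF, 17 of 27 genes rose in the libraries labelled HMGB2 siRNA (HMGB2-high) and 0 fell. The list also holds SMC5, SMC6, LMNA, LMNB1, LMNB2 and LBR, which are not cohesin or condensin genes. Those that rose included the cohesin release factor WAPL (1.71-fold) and the condensin subunits NCAPD2 (1.62-fold) and NCAPG (1.65-fold). The condensin core subunit SMC4 had 334 ± 2.7 against 223 ± 4.0 CPM (SD, n = 2 each). The camera adjusted p of this list was 1.82e-08, and the adjusted p was 0.330 with an estimated correlation. Of 32 homologous recombination and Fanconi anaemia genes, 16 rose and 1 fell. FANCD2 was 1.95-fold, the checkpoint kinase CHEK2 1.57-fold and the exonuclease EXO1 1.45-fold higher. The list also holds DNA polymerase theta (POLQ), an enzyme of alternative end joining, which was 2.09-fold higher. The camera adjusted p was 0.00121, the adjusted p was 0.376 with an estimated correlation, and the call ended when genes with 3′UTR words associated with the fold changes were left out (adjusted p = 0.0767). The 14 members then left had a median log2 fold change of 0.15, with 6 higher and 1 lower, against 0.22 for all 32. The words were chosen for higher fold changes in these same data, so this loss is no independent test. NCAPG also stands in the mitotic list, and WAPL, NCAPG, NCAPD2 and FANCD2 each overlap exons of a gene on the opposite strand.

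Replication-dependent histone genes, whose transcripts mostly end in a stem-loop without a poly(A) tail, went the other way. Of 23 tested members 15 were lower in the libraries labelled HMGB2 siRNA (HMGB2-high), 0 were higher and 8 did not pass, with a median log2 fold change of -0.89. H2AC6 had 11.7 ± 0.48 against 31.7 ± 0.21 CPM and H2BC5 17.2 ± 0.87 against 36.4 ± 0.66 CPM (SD, n = 2 each). H2BC12, the most abundant of the named members, had 97.0 ± 6.3 against 169 ± 4.7 CPM (SD, n = 2 each), and H1-2 had a log2 fold change of -0.88 ± 0.09 (SE). The camera adjusted p was 2.64e-08, and the adjusted p was 0.330 with an estimated correlation, which came out at -0.017. Members of this family are near-identical in sequence, so reads may be split between them, and 27 of the 50 listed genes had too few counts to test.

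Cholesterol synthesis genes were also lower in the libraries labelled HMGB2 siRNA (HMGB2-high), with 17 of 24 called lower, 2 higher and a median log2 fold change of -0.29. MSMO1, a sterol demethylation enzyme, had 70.8 ± 3.1 against 141 ± 8.8 CPM (SD, n = 2 each), MVD had a log2 fold change of -0.54 ± 0.07 and ACAT2 of -0.49 ± 0.07 (SE). INSIG1, which retains the SREBP activation complex in the endoplasmic reticulum, went the other way and was 1.97-fold higher. The 3′UTRs of INSIG1 and MSMO1 both carried the heptamer GACAAAG. The camera adjusted p was 1.17e-05, and the adjusted p was 0.376 with an estimated correlation. ACAT2 overlaps exons of SOD2 and TCP1 on the opposite strand. Of 13 mitochondrially encoded protein genes, 8 fell and 0 rose, with a median of -0.19 (camera adjusted p = 0.000836; adjusted p = 0.579 with an estimated correlation). The named members were ND4L (-0.35), ND4 (-0.27), ND3 (-0.22) and ND5 (-0.21, log2 fold changes), subunits of respiratory complex I, of which ND4 and ND4L share exonic sequence. Mitochondrial genes took 4.56 ± 0.182% of counts in the libraries labelled HMGB2 siRNA and 5.31 ± 0.0725% in those labelled scramble (SD, n = 2 each), and without replicate 1 labelled HMGB2 siRNA neither this list (median -0.09, adjusted p = 0.0825) nor its 4 named members were called (ND4L -0.22, ND4 -0.20, ND3 -0.18 and ND5 -0.18). Without replicate 2 of that label ND3 (-0.26, adjusted p = 0.0738) and ND5 (-0.23, adjusted p = 0.125) also lost the call.

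Among 24 epithelial genes, 11 rose in the libraries labelled HMGB2 siRNA (HMGB2-high), 2 fell and 11 did not pass, and 12 and 2 passed when adjusted over the list alone. E-cadherin (CDH1) was 2.31-fold higher, with 19.6 and 20.5 CPM against 8.90 and 8.40 CPM in the single libraries. The tight junction gene CLDN4 was 1.75-fold, the keratin KRT19 1.61-fold and desmoplakin (DSP) 1.38-fold higher. The camera adjusted p was 0.00193, and the adjusted p was 0.376 with an estimated correlation. Of 28 genes of the unfolded protein and ATF4 responses, 13 rose and 3 fell (camera adjusted p = 0.00193; adjusted p = 0.579 with an estimated correlation). They included SLC7A11, the light chain of the cystine transporter, at 2.79-fold, and its heavy chain partner SLC3A2 at 1.63-fold, with the stress-induced genes DDIT4 at 1.70-fold and NUPR1 at 1.72-fold. Of 21 heat shock genes, 8 rose and 0 fell (camera adjusted p = 0.0079; adjusted p = 0.394 with an estimated correlation), among them the chaperone HSPA4L at 2.03-fold, DNAJB4 at 1.56-fold and HSPB1 at 1.27-fold. Of 31 type I interferon response genes, 11 rose and 2 fell, with IFI6 at 1.94-fold, SAMD9 at 2.69-fold and IFIT3 at 1.71-fold. The interferon list had a camera adjusted p of 0.0111 and an adjusted p of 0.579 with an estimated correlation, and its call also ended without scramble replicate 2 (median 0.24, adjusted p = 0.171) and without genes carrying the associated 3′UTR words (adjusted p = 0.309). The median was 0.28 over all 31 members and 0.17 over the 16 without such words, of which 3 were higher and 2 lower. Because the words were chosen on these fold changes, that split is no independent test. DSP, SLC7A11 and DNAJB4 share exonic sequence with a gene on the opposite strand, and HSPA4L with a gene on its own strand. The 3′UTRs of DSP, SLC7A11, NUPR1, HSPA4L and IFIT3 carried GACAAAG, ATAGTAA or AATAGTA, and those of CDH1, CLDN4, KRT19, SLC3A2, DDIT4, DNAJB4, HSPB1, IFI6 and SAMD9 did not. DNAJB4 and SAMD9 did carry others of the 9 associated words.

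**Figure D3:**
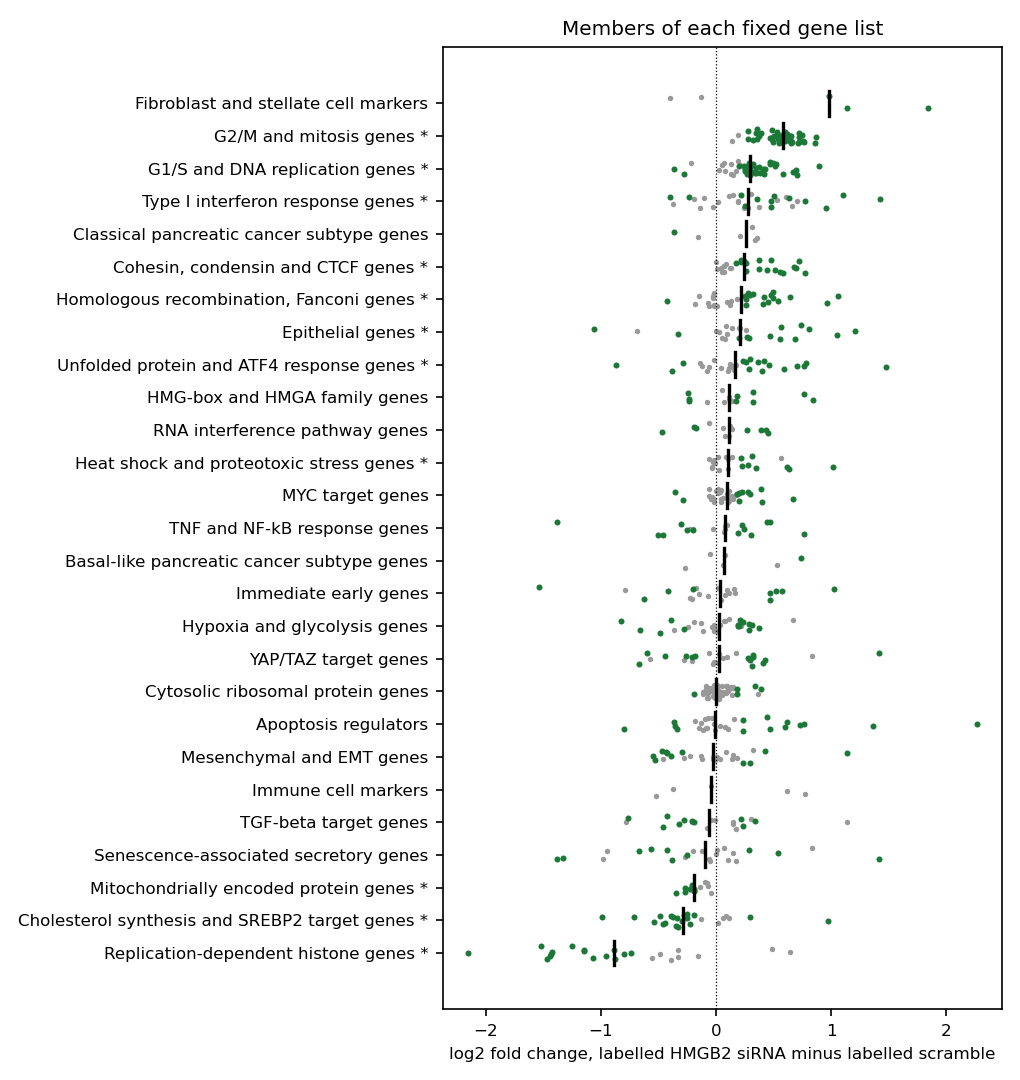
Log2 fold change (horizontal axis, labelled HMGB2 siRNA minus labelled scramble) of each tested member of the gene lists reported here that had at least 5 tested members; green points passed the gene test, grey points did not, black bars are medians and asterisks mark lists called by camera with its preset correlation. The mitotic list lies to the right of 0 with a median of 0.58 and the histone list to the left with a median of -0.89.

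The other lists reported here were not called by camera in the comparison of the libraries labelled HMGB2 siRNA (HMGB2-high) with those labelled scramble, although single members moved. Among 29 apoptosis regulators, 10 were higher and 4 lower, with cytochrome c (CYCS) at 1.54-fold and BIRC3 at 1.70-fold (camera adjusted p = 0.0637). The apoptosis list was called higher without each of the 4 libraries in turn, with adjusted p from 0.00245 without replicate 1 labelled HMGB2 siRNA to 0.026 without scramble replicate 2, while its median stayed near 0, and its adjusted p was 0.606 with an estimated correlation. The 12 members with any of the associated 3′UTR words had a median log2 fold change of 0.53, and the 17 without had -0.10, with 1 higher and 4 lower. A gap in this direction is favoured by the choice of the words on these fold changes, so it is a description only. Of 24 senescence-associated secretory genes, 3 were higher and 7 lower, with FGF2 at 2.68-fold higher and CXCL1, CCL2 and LIF at log2 fold changes of -1.38, -0.67 and -0.57 (camera adjusted p = 0.192). The NF-kB list had 7 of 20 members higher and 6 lower (7 and 7 when adjusted over the list alone; camera adjusted p = 0.731), the higher ones including BIRC3 at 1.70-fold, BIRC2 at 1.38-fold and TNFAIP2 at 1.36-fold. The immediate early list had 5 of 22 members higher and 4 lower (camera adjusted p = 0.979), with JUN at -0.63 and DUSP1 at 0.52 on the log2 scale. FGF2 overlaps exons of NUDT6, and LIF those of LIF-AS1 and LIF-AS2, on the opposite strand.

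Mesenchymal genes were 4 higher and 7 lower of 26 in the libraries labelled HMGB2 siRNA (HMGB2-high), with log2 fold changes of -0.53 for the collagen crosslinking enzyme LOXL2, -0.47 for SPARC, -0.55 for the membrane protease MMP14 and -0.39 for the integrin ITGA5 (camera adjusted p = 0.198, and 0.0096 without scramble replicate 2). In the list of 26 YAP/TAZ targets, 8 were higher and 6 lower (8 and 8 when adjusted over the list alone; camera adjusted p = 0.795), and the lower ones included WWTR1, which encodes TAZ itself, at -0.67, NT5E at -0.60 and CCN2 at -0.45. The TGF-beta list of 20 held 3 higher and 7 lower members (7 and 7 when adjusted over the list alone; camera adjusted p = 0.357), with BHLHE40 at -0.77 and TGFBR1 at -0.46. For hypoxia and glycolysis, 9 of 30 genes were higher and 5 lower (10 and 5 when adjusted over the list alone; camera adjusted p = 0.819), the lower ones including ALDOC at -0.83 and PFKFB4 at -0.66. Of 40 MYC targets, 9 were higher and 2 lower (8 and 2 when adjusted over the list alone; camera adjusted p = 0.0637, and 0.00733 without scramble replicate 1), and NOP58, a box C/D ribonucleoprotein component, was 1.59-fold higher. Among 59 ribosomal protein genes, 4 were higher and 1 lower (2 and 0 when adjusted over the list alone; camera adjusted p = 0.789, and 0.0133 without scramble replicate 1), with RPS25 at 1.31-fold. The 13 RNA interference genes had 4 higher, among them the argonautes AGO2 at 1.31-fold and AGO3 at 1.35-fold, and 3 lower (camera adjusted p = 0.261). In the HMG list, tested without HMGB2, 6 of 15 genes were higher and 3 lower (camera adjusted p = 0.178), with HMGN3 at 1.70-fold and HMGN2 at 346 ± 7.3 against 277 ± 15 CPM (SD, n = 2 each). BHLHE40, LOXL2, SPARC, ITGA5, RPS25, AGO2 and HMGN3 share exonic sequence with a gene on the opposite strand, and AGO3 and PFKFB4 with a gene on their own strand. For every other list reported here the counts over all genes and adjusted over the list alone were equal. The sign of the median, the mean or the camera test differed for the NF-kB, classical subtype, hypoxia, YAP/TAZ, apoptosis, immediate early, ribosomal and immune lists.

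Markers of pancreatic cancer subtypes and of other cell types were mostly at low levels. Only 6 of 25 classical and 6 of 25 basal-like subtype genes had enough counts to test, and of these AGR2 (-0.36) was lower and KRT7 (0.74) higher on the log2 scale in the libraries labelled HMGB2 siRNA (HMGB2-high), with camera adjusted p of 0.795 and 0.731. The KRT7 call was lost with DESeq2 (adjusted p = 0.0517) and without replicate 1 labelled HMGB2 siRNA (adjusted p = 0.0736). Of 21 immune cell markers 5 could be tested (camera adjusted p = 0.979). The most abundant, CD68, had 107 ± 3.2 against 110 ± 16 CPM (SD, n = 2 each) and did not pass, although without scramble replicate 2 it was called lower (adjusted p = 0.0198). Of 13 endothelial markers 2 could be tested, ERG and ESAM, both below 2 CPM in each library, and neither passed (adjusted p = 0.20 and 0.55). Of 20 acinar and islet markers 0 had enough counts to test. Of 15 fibroblast and stellate cell markers 5 could be tested and 3 rose (camera adjusted p = 0.42), namely THY1 with 3.98 ± 0.72 against 1.98 ± 0.22 CPM, COL3A1 with 2.55 ± 0.30 against 1.17 ± 0.045 CPM and PDGFRB with 0.950 ± 0.17 against 0.255 ± 0.089 CPM (SD, n = 2 each). The PDGFRB call was lost without any of the libraries but scramble replicate 1, that of COL3A1 without replicate 1 labelled HMGB2 siRNA and that of THY1 without replicate 2 of that label. KRT7, CD68, COL3A1 and SMAD4 share exonic sequence with a gene on the opposite strand. SMAD4 had a log2 fold change of -0.12 ± 0.09 (SE) and did not pass. CDKN2A had 0 counts in all 4 libraries, which allows up to 0.0954 to 0.146 CPM.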

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

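The thinned libraries and the lists without genes carrying the associated 3′UTR words were tried only after seeing the data, and all other alternatives were set before. HMGB2 stayed higher in the libraries labelled HMGB2 siRNA and past the threshold in every alternative. The number of genes called lower was 1286 with DESeq2, and with a test against a 1.5-fold change 213 genes were higher and 45 lower, where the tested hypothesis itself demands larger changes. Leaving out 1 library at a time gave 1481 to 2904 genes higher and 903 to 2291 lower, and the lone library of a group was then assumed to vary like the other group. The lowest counts came without either library labelled HMGB2 siRNA, where the spread rested on the 2 scramble libraries alone. These differed more from each other than the libraries labelled HMGB2 siRNA did (chi-square per degree of freedom of 5.65 against 3.13). No separate test of this cause was run. The other scalings and filters, limma-voom and thinning moved neither count by more than 1.5 times, and scaling moved the median of all genes by at most 0.051 on the log2 scale. With the replicate block 2446 genes were higher and 2011 lower. Same-numbered libraries did not deviate together (correlation across genes of -0.014), so the numbers were not taken to pair the libraries. With an estimated correlation 0 lists were called higher and 0 lower, where 3 lists had an unadjusted p under 0.05 and only 2 residual degrees of freedom were left. The estimate was -0.017 for the histone, -0.021 for the cohesin, -0.016 for the recombination and 0.0098 for the cholesterol list. These lie under the preset 0.01, so a larger correlation was not why those calls ended. It was 0.59 for the G2/M and 0.51 for the G1/S list. By fry 2 lists were called higher (cohesin, condensin and CTCF genes, and homologous recombination and Fanconi genes). Fry also called the histone and cholesterol lists lower. DESeq2, limma-voom and the 1.5-fold test gave no separate list result. The senescence-associated secretory list was called lower without genes carrying the associated words (adjusted p = 0.0266). Those words were chosen for higher fold changes here, so leaving out their carriers favours a lower list. With the replicate block the apoptosis list was called higher (adjusted p = 0.00892), and without a low-count filter the apoptosis, MYC, hypoxia and HMG lists were (adjusted p from 0.00027 to 0.0416). Of 123 named genes past the threshold, 0 changed direction, 82 lost the call in at least 1 alternative and 15 did so in an alternative other than the 1.5-fold test. In the simulated counts 67.3% of 1.5-fold changes were recovered, but only 50 genes were changed at each fold there, against 4671 genes called here. With so few changed genes a smaller unadjusted p was needed to pass. The simulated share therefore does not give the recovery in these libraries.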

Other observations

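The comparison of genes without a symbol was chosen after seeing the data, while the tests of each explanation below were set before their results were seen. Genes that carry only a locus number, most of them uncharacterised, were called mainly in the direction opposite to HMGB2. Of 840 such genes tested, 99 were lower and 24 higher in the libraries labelled HMGB2 siRNA (HMGB2-high), so 80.5% of those called were lower, against 44.8% of called genes with a symbol (odds ratio 5.09, 95% interval 3.22 to 8.34, Fisher's exact p = 1.81e-15, two-sided). Among called genes with a mean of at most 4.96 CPM, the shares were 84.8% of 92 and 64.5% of 473 (Fisher's exact p = 8.36e-05, two-sided). Genes are not independent replicates, so these p-values describe the 4 libraries.

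Each deposited table carries the other treatment in its name and count header than the label of its sample. A candidate explanation is that the labels or the tables of both groups were exchanged, which needs HMGB2 to be higher in both libraries labelled HMGB2 siRNA. The HMGB2 log2 fold change was 3.075, with 127.9 and 133.8 CPM against 15.7 and 15.3 CPM, as an exchange of both groups requires. If the groups were exchanged, every direction given for the labels turns over, and the G2/M genes would be lower where HMGB2 was depleted. Whether the labels or the tables were at fault stays open.

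More genes were higher than lower in the libraries labelled HMGB2 siRNA in a test against a 1.5-fold change (213 against 45), although the called genes with more than 2-fold changes were nearly balanced (233 against 208). A candidate explanation is silencing, in the libraries labelled scramble, of transcripts that match the seed of an siRNA acting there. The 3′UTR heptamer most associated with the fold change was GACAAAG (t = 14.07, 1439 genes), followed by ATAGTAA (t = 12.47) and AATAGTA (t = 12.20), and all 3 occur in HMGB2 transcripts, which contain 11.4% of all heptamers. The next words, AGACAAA (t = 8.88) and TAGTAAT (t = 8.01), do not occur there, so that 3 of the top 5 words did, and 4 of the 9 words associated with higher values at a Bonferroni-adjusted threshold of 0.001. ATAGTAA, AATAGTA and TAGTAAT overlap each other, and AGACAAA overlaps GACAAAG. These counts are therefore not of independent matches to set against the 11.4%. The highest absolute t in 20 permutations of the fold changes over genes was 5.65. AGTAATG, the last of the 9 words, had a t of 5.55, below that value. At least 1 of the 9 words occurred in 6041 of 12091 genes. Between libraries of the same label GACAAAG, ATAGTAA and AATAGTA reached at most 2.61. In each of the 4 pairs of libraries with different labels these 3 words ranked within the top 3. Of the 233 genes called more than 2-fold higher, 195 had a matched 3′UTR. Of these, 125 (64.1%) carried at least 1 of the 3 words, against 26.1% of all genes with a 3′UTR. The words were chosen on these same fold changes, so this share is a description and not a further test. Direct effects of HMGB2 on these genes stay open, and the siRNA sequences were not used here.

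The median log2 fold change was 0.169 for 462 genes with both word families, 0.088 for 977 genes with GACAAAG alone and -0.012 for 8934 genes with neither. In the opposite direction, AGTACAA passed the same threshold with lower values in the libraries labelled HMGB2 siRNA (t = -7.81) and does not occur in HMGB2 transcripts. Among the named genes, MAT2B, SEC23A, FGF2, POLQ and FANCD2, which were higher, carried at least 1 of the 3 words. So did the higher genes WAPL, SLC7A11, NUPR1, HSPA4L, IFIT3, INSIG1, CYCS, BIRC3, NOP58, AGO2 and AGO3, among others. MSMO1, WWTR1 and SPARC, which were lower (log2 fold changes of -0.99, -0.67 and -0.47), carried at least 1 as well. CDH1, PLK1, RRM2, NCAPD2, SLC3A2, DDIT4 and HSPB1 were higher and carried none. Direct silencing through these 9 words did not account for the G2/M genes as a group. The 25 members without any of the words had a median log2 fold change of 0.593 (95% interval 0.494 to 0.620) and 24 of them rose. That interval resamples genes and does not measure the spread between libraries. Leaving out 1 library at a time put the median of the whole list between 0.50 and 0.69. An indirect effect through a silenced regulator, or an effect of HMGB2 itself, may still underlie that group and was not tested.

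Replication-dependent histone transcripts were lower in the libraries labelled HMGB2 siRNA, opposite to the replication genes. A candidate explanation is more carry-over of RNA without poly(A) tails into the libraries labelled scramble, which would raise other such RNAs there as well. Over 7 tested RNAs listed beforehand as of this kind, the median log2 fold change was -0.081 (95% interval -0.356 to 0.080). This was above the -0.44 that was set beforehand as the bound and above the histone median of -0.89. Another 28 such RNAs had too few counts to test, and SCARNA12, SNORA73A and SNORA73B, among the 7, had SE of 0.29 to 0.31. So few and imprecise values cannot decide whether carry-over was the whole source. The 3 most abundant of the 7 did lie in the direction of carry-over, with log2 fold changes of -0.36 (RNR2, adjusted p = 7.75e-05), -0.18 (RNR1, adjusted p = 0.0448) and -0.40 (RN7SK, adjusted p = 0.061). RNR1 and RNR2 are mitochondrial ribosomal RNAs, which can carry short A tails, so they may not measure carry-over. The mitochondrial share of counts was lower in the libraries labelled HMGB2 siRNA as well. Carry-over, as a part or the whole source, therefore stays open. A change in the share of histone transcripts that end in a poly(A) tail, or in their transcription, stays open as a hypothesis and was not tested.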
